A study of Homo sapiens with 4 samples.

How the data were processed

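Gene expression was measured on 4 Affymetrix arrays, 1 each for the colon cancer cell lines HT29 and Colo205 and for a derivative of each line that had been grown in rising concentrations of PLX4720, a kinase inhibitor, until it was resistant. Per the labels' protocols, cells were grown in medium with 10% serum, the resistant derivatives were kept without PLX4720 for 24 h before harvest, total RNA was purified on columns, and biotin-labelled cRNA was hybridised. The arrays fall into the groups parental and resistant, with HT29 numbered as replicate 1 and Colo205 as replicate 2 of each group. The labels do not say whether the cultures of one line were independent of each other. There are no replicates within a line and status. A single gene's p-value below therefore rests on the spread between the 2 lines' differences, which limma combines with that of all genes. The gene's own spread has 1 degree of freedom and the spread taken from all genes 2.54. The p-values by which gene lists were called set a list's genes against the other genes. They do not measure the spread between replicates.

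The deposited table holds log2 expression values for 54675 probe sets, summarised and normalised by the authors. The log2 scale was read from the values, which run from 2.51 to 14.88 on a continuous scale. The submitters' processing notes name MAS5 and RMA without a role or a version, and the background correction is not given in the sources used here. The number of arrays, not a read depth, limits the precision.

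Probe sets were named through the platform annotation supplied with the table. Of them, 41091 named 1 gene, with control probe sets left out, 1801 named several and 11777 named none. There were 62 control probe sets, and those of them without a gene name are part of the 11777. The gene symbols were set against the RefSeq gene table of assembly GRCh38.p14. It held the gene identifiers of 41037 of the probe sets naming 1 gene and changed the symbol of 0. That table was otherwise used only to bring the symbols of the gene lists up to date and for the order of genes along chromosomes. Probe sets naming several genes or none were left out of the comparisons, and each gene was represented by its probe set with the highest mean over the 4 arrays. Genes whose highest value over the arrays lay below 5.73, the median of all values in the table, were left out, which kept 13651 of 19775 genes.

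Within each line, the difference was the resistant minus the parental log2 value, and genes were counted at 2-fold or more. With 1 array on each side there is no test for these differences. As a measure of technical scatter, the spread of the differences between probe sets of one gene was pooled over 6615 genes with several probe sets. It had an SD of 0.30 in each line. Across both lines, resistant and parental arrays were compared with limma 3.58.1 in R 4.3.3, with the cell line as a block, which pairs each derivative with its own parent and leaves 1 residual degree of freedom. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

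The 30 gene lists were tested across both lines with camera, a competitive test in limma, at a preset correlation of 0.01 between genes. A correlation estimated from the data and the test fry were alternatives. With an estimated correlation, camera uses the 1 residual degree of freedom of the fit. A call lost there need not come from correlation between genes. Within each line, a list's median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. List members adjusted over the list alone are given beside those adjusted over all genes.

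The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took 7 genes by name, the 12 genes with the largest difference in each direction in each line whose probe sets all pointed the same way, the 10 genes in each direction with the largest smaller-of-the-pair difference over both lines, the 5 such genes for each opposite orientation, the 3 highest and 3 lowest members of each list by their mean, and any gene past the adjusted threshold. Of the 7 genes, 4 are described and the others are not reported here. Genes outside this rule are named in the text as chosen after their values were seen.

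The procedures were tested on simulated arrays made from the measured parental values of 13651 genes, with 50 genes changed at each fold. The first kind of noise was drawn from the real differences between the lines. With it, limma with the block called 0% of the genes changed 4-fold in both lines. It called 76% of those changed 8-fold and 96% of those changed 16-fold. This noise had opposite signs in the lines, so it cancelled in their mean. That 0 unchanged genes were called therefore followed from the setting and says nothing of false calls. The percentages likewise hold only for means free of noise. With equal noise for every gene, taken from the scatter between probe sets, it called 94% of the genes changed 2-fold and 4 of 13334 unchanged genes. In that setting limma took all genes to share the same variance. The real fit did not, with 2.54 prior degrees of freedom, so the 94% does not carry over to it. A list shifted down as a whole was called by camera under both kinds of noise, of which the first left the list's mean free of noise. The list shifted was that of cholesterol biosynthesis, by a size near its real medians. Noise was drawn independently between genes, so the run says nothing of lists whose genes are correlated. Alternatives covered the filter, the choice of probe set, quantile normalisation, median centring, the fold threshold, the block, the variance model and the list test.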

Results

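HT29 and Colo205 are established colon cancer cell lines. The series compared each line with a derivative that had acquired resistance to PLX4720, and asked how expression in the resistant cells differed from that in their parents. There were 2 parental and 2 resistant arrays, 1 for each line and status, with 13651 genes kept. The array medians over all probe sets lay within 0.05 of each other on the log2 scale.

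Each derivative lay nearer its own parent than the other line. Across genes, which are not independent replicates, resistant HT29 had a Pearson correlation of 0.971 with parental HT29 and of 0.849 with parental Colo205. Resistant Colo205 had a correlation of 0.976 with its own parent and of 0.873 with parental HT29. Of 861 genes that differed 4-fold or more between the parents, 92.7% lay nearer their own parent in resistant HT29 and 90.5% in resistant Colo205. LDHB, a lactate dehydrogenase subunit, read 13.84 in parental HT29 and 5.23 in parental Colo205, and PLA2G2A, a secreted phospholipase, read 5.89 and 14.26; both were chosen after their values were seen.

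The largest differences in resistant HT29 were mostly in genes that were higher than in the parent. CDH17, the intestinal cadherin, read 5.30 in parental and 11.24 in resistant HT29, a difference of 5.94 on the log2 scale, and MUC17, a membrane mucin of enterocytes, was higher by 4.80. DHRS9, a retinol dehydrogenase, was higher by 5.30, the scaffold protein gene AKAP12 by 4.83 and the iron-exporting ferroxidase gene HEPH by 4.78. PRPS2, which makes the sugar phosphate precursor of nucleotides, read 9.75 in the parent and 4.29 in the derivative, and NNMT, which methylates nicotinamide, read 9.26 and 5.45. Readings below the filter value of 5.73 were not shown to lie above background, so differences that rest on one have no exact size or rank. This holds for 6 of the 12 largest positive and 6 of the 12 largest negative differences in HT29, CDH17, MUC17, PRPS2 and NNMT among them, and for 4 and 8 in Colo205.

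In all, 467 genes were 2-fold or more higher and 235 were 2-fold or more lower in resistant HT29, or 5.14% of the genes. At 4-fold or more the counts were 91 higher and 32 lower. Further genes among the 12 with the largest positive differences were AHNAK2 (4.73), SPRR1B (4.67), SNX10 (4.41), GEM (4.15), IGFL2 (4.03), the collagenase gene MMP1 (3.78) and PHLDB2 (3.75). Among the 12 with the largest negative differences were ADAMTS6 (-3.50), ZDHHC2 (-3.27), FRY (-3.20), COL9A3 (-3.10), SLC7A2 (-3.05), SBSPON (-3.05), DPYSL2 (-2.97), the growth factor gene FGF9 (-2.95), SLC4A4 (-2.82) and INSIG1 (-2.76). SNX10 lies in a part of chromosome 7 whose genes had a median difference of 0.56 in HT29, INSIG1 and MUC17 in the rest of it, with a median of -0.21, and FRY in a run of chromosome 13 genes with a median of -0.35. These differences have no test, and the one other MUC17 probe set past the filter differed by 0.07. The probe sets of PRPS2 ranged from -5.46 to -3.77, those of NNMT from -3.81 to -2.09 and those of FRY from -3.20 to -1.84.

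Markers of colonocyte and enterocyte differentiation stood apart in HT29. Their median difference over 15 measured genes was 0.42, at percentile 99.99 of random lists, and 7 of the 15 were 2-fold or more higher, among them FABP1 (2.30), KRT20 (1.58), CDX2 (1.35) and DPP4 (1.20), while CEACAM1 was at -0.84. YAP-TEAD targets had a median of 0.38 over 18 genes, at percentile 99.99, with NT5E at 1.57, F3 at 1.54, MYOF at 1.51 and GADD45B at -0.56. Interferon-stimulated genes had a median of -0.51, below every random list, with 20 of 24 lower. IFIT1 was at -1.66, IFI44 at -1.65 and HERC6 at -1.19, while OASL was at 1.54. Epithelial markers (0.15), receptor tyrosine kinase ligands (0.24) and antigen presentation genes (0.17) had medians above the central 95% of random lists. Of the 30 lists, 9 lay outside that range in HT29. On the simulated HT29 arrays 3 lists that had not been shifted also lay outside it. The ligand list held both PDGFA, at 1.71, and FGF9, at -2.95. KRT20, CDX2, DPP4, NT5E and HERC6 were chosen after their values were seen.

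Resistant Colo205 had more genes that were lower than genes that were higher. SPRR1B, a precursor of the cornified envelope of squamous epithelium, read 5.01 in parental and 12.30 in resistant Colo205, a difference of 7.29, and SPRR3 and SPRR1A of the same family were higher by 5.14 and 4.68. The other 3 of the 6 measured SPRR genes were at -0.03 (SPRR2B), 0.22 (SPRR2G) and 0.09 (SPRR4), and were chosen after their values were seen. BCAT1, which begins the breakdown of branched-chain amino acids, was higher by 5.78, and the cell adhesion genes CEACAM6 and CEACAM5 by 4.33 and 3.16. GLUL, glutamine synthetase, read 12.34 in the parent and 5.77 in the derivative, with probe sets from -6.57 to -1.94. PROM1, a stem cell surface marker, read 9.48 and 4.39, and GZMA, a serine protease best known from cytotoxic lymphocytes, read 10.53 and 3.98. BCAT1, PROM1 and GZMA rest on a reading below the filter value, as do SPRR1B, UGT2B4 and FZD10.

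In all, 124 genes were 2-fold or more higher and 343 were 2-fold or more lower in resistant Colo205, or 3.42% of the genes. At 4-fold or more the counts were 25 higher and 65 lower. When each array was centred on its median, which moved the median of all genes in Colo205 by 0.12, the split was 166 higher and 271 lower. The other genes with the largest positive differences were MAOB (4.03), ETFRF1 (3.54), the interferon-induced gene IFI27 (3.40), AKAP12 (3.40), REG4 (3.15) and GPAT3 (2.93). Those with the largest negative differences were UGT2B4 (-6.12), STRIT1 (-4.80), the WNT receptor gene FZD10 (-4.72), DNAJC12 (-4.37), FKBP11 (-4.26), the trypsin inhibitor gene SPINK1 (-4.10), POU2AF1 (-3.54), MATN2 (-3.37) and NFE2 (-3.37). BCAT1 and ETFRF1 lie in 1 run of neighbouring chromosome 12 genes, 7 of 8 of which were 2-fold or more higher in this line. The run was picked for these higher genes. FZD10, FKBP11 and NFE2 lie elsewhere on chromosome 12, where the other 725 genes had a median of -0.26 in Colo205. The probe sets of BCAT1 ranged from 2.15 to 5.97, those of DNAJC12 from -4.37 to -1.85 and those of FKBP11 from -4.43 to -1.07. Genes of the SPRR, CEACAM and UGT families are similar in sequence, so their probe sets can read more than 1 member.

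Amino acid and stress response genes were lower in resistant Colo205, where the 24 poly-A spike control probe sets were also lower, with a median of -0.72. Of 25 measured genes of the ATF4 and unfolded protein response list, 9 were 2-fold or more lower, and the median of -0.65 lay below every random list. DDIT4 (-2.71), PHGDH (-1.99), ASNS (-1.83) and CTH (-2.08) were among them. Genes of the NRF2 and xenobiotic metabolism list had a median of 0.52 over 21 genes, above every random list, with ALDH3A1 at 1.31, GCLM at 1.26, CYP3A5 at 1.03 and SULT1A1 at -0.74. Interferon-stimulated genes had a median of 0.22, at percentile 99.98, with 14 of 24 higher, IFI27 at 3.40 and GBP1 at -2.07. Of the 24, 7 were lower in both lines and 1 higher in both, and the difference between the lines was not tested. Cyclin-dependent kinase regulators (0.19) and ERK pathway output genes (0.15) lay above the central 95% of random lists, and RAS-RAF-MEK-ERK components (-0.27) lay below it. Of the 30 lists, 8 lay outside that range in Colo205. CTH and ALDH3A1 were chosen after their values were seen.

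The 2 resistant lines shared a set of differences. SPRR1B, SPRR3 and SPRR1A were higher in both, as were AKAP12 (4.83 in HT29 and 3.40 in Colo205), the matrix protein gene TNC (3.46 and 2.91), CEACAM5 (2.87 and 3.16), MAOB (2.48 and 4.03), REG4 (2.39 and 3.15), S100A2 (3.46 and 2.18) and the protease inhibitor gene SERPINE2 (3.60 and 1.95). Lower in both were the nuclear receptor gene NR2F1 (-2.62 and -2.50), TESC (-2.35 and -2.10), POU2AF1 (-2.04 and -3.54), the sialyltransferase gene ST6GAL1 (-1.86 and -2.43), ACSM3 (-2.37 and -1.67) and PROM1 (-1.57 and -5.09). The homeobox genes HOXB8 (-1.50 and -1.62) and HOXB9 (-1.53 and -1.46), ACSL1 (-1.65 and -1.38) and PDZK1 (-1.38 and -2.84) complete the 10 lower genes.

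**Figure D1:**
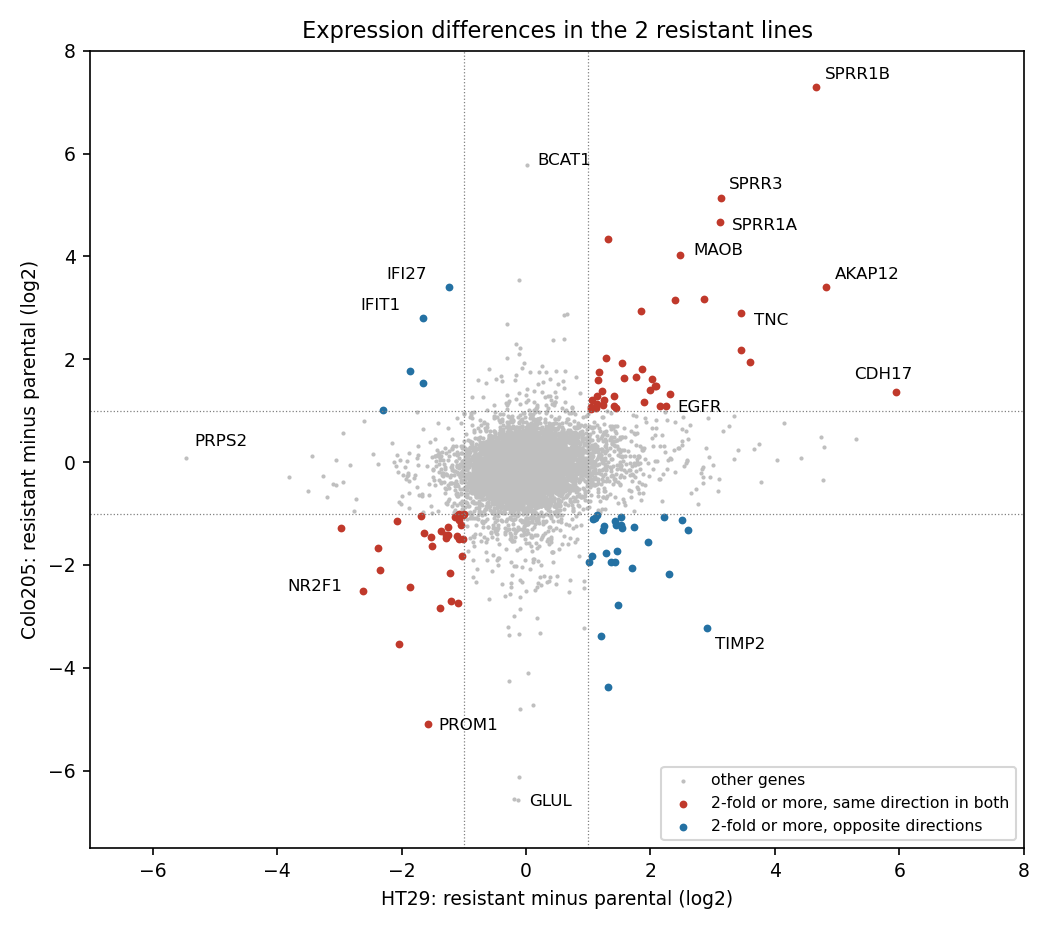
Each point is 1 of 13651 genes, placed by its resistant minus parental log2 difference in HT29 (horizontal) and Colo205 (vertical), with dotted lines at 2-fold. The 40 genes higher in both lines and the 32 lower in both are red, the 32 in opposite directions are blue, and SPRR1B lies farthest up at 7.29 in Colo205.

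**Figure D2:**
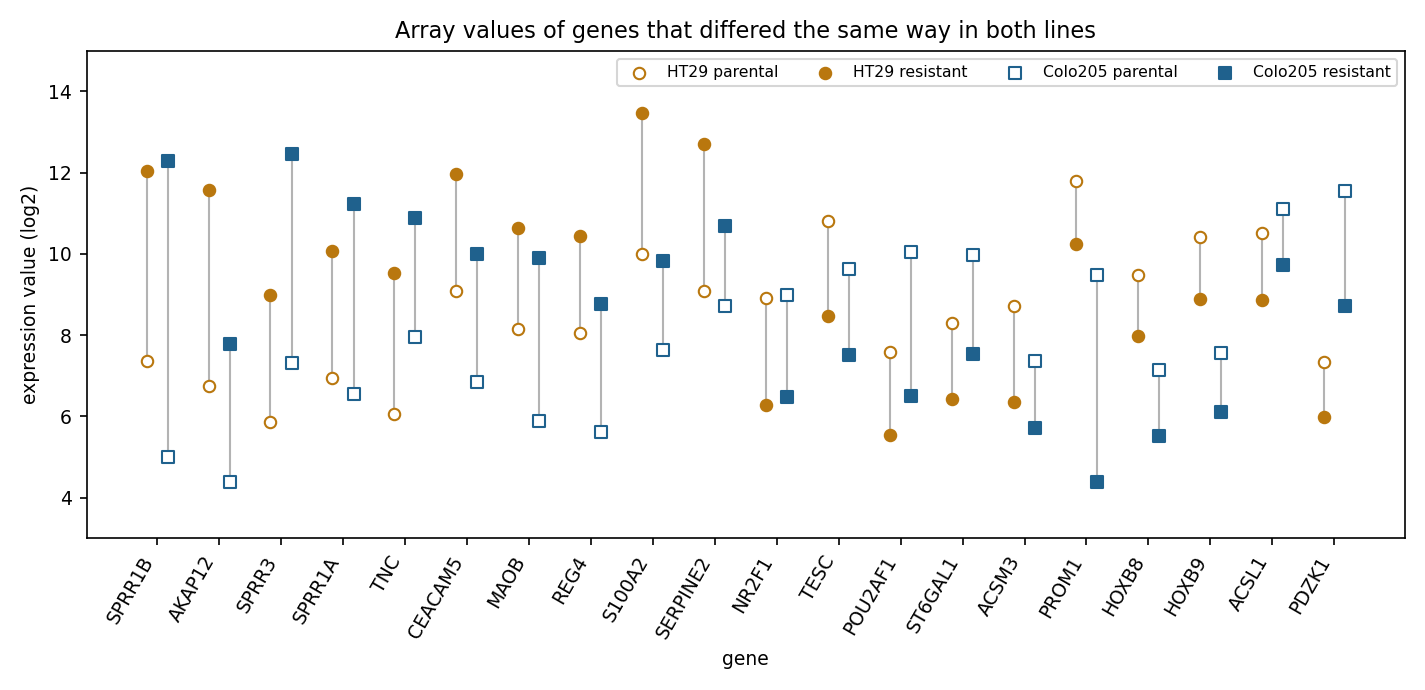
Log2 expression value on each of the 4 arrays for the 10 genes higher and the 10 genes lower in both resistant lines, with parental arrays as open and resistant arrays as filled symbols and a line joining each pair. SPRR1B read 7.36 and 12.03 in the HT29 pair and 5.01 and 12.30 in the Colo205 pair.

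Altogether 40 genes were 2-fold or more higher in both lines, where independent lists of these sizes would share 4.24, and 32 were lower in both, against 5.90. Another 27 were higher in HT29 and lower in Colo205, against 11.7, and 5 were lower in HT29 and higher in Colo205, against 2.13. Across genes, the differences of the lines had a Pearson correlation of 0.175 and a Spearman correlation of 0.178. No gene passed the adjusted threshold in limma (0 genes, smallest adjusted p = 0.706), whereas 928 genes had an unadjusted p under 0.05, 372 higher and 556 lower, with 683 expected by chance. With a mean-variance trend the counts were 0 adjusted and 918 unadjusted, with a robust trend 0 and 917, and without the block 0 and 131. The 24 poly-A spike control probe sets were lower in the resistant array in both lines, with medians of -0.43 in HT29 and -0.72 in Colo205. The 4 measured mitochondrially encoded transcripts, chosen after their values were seen, were higher in both, with medians of 0.51 and 0.47 and ND6 at 0.32 and 1.76. The probe sets of AKAP12 past the filter ranged from 0.18 to 5.36 in HT29 and from 0.12 to 3.40 in Colo205, those of SPRR3 from 0.62 to 3.13 and from 0.47 to 5.14, and those of CEACAM5 from 0.09 to 2.87 and from 0.04 to 3.16. Those of HOXB9 ranged from -1.46 to 0.15 in Colo205 and those of POU2AF1 from -2.04 to -0.49 in HT29. TESC also lies on chromosome 12.

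Of the genes fixed by name, EGFR, the epidermal growth factor receptor, read 8.63 in parental and 10.89 in resistant HT29, and 7.41 and 8.50 in the Colo205 pair. Its mean difference was 1.68, with a limma 95% interval from 0.67 to 2.68 over the 2 pairs and an adjusted p = 0.706. Its 8 probe sets past the filter ranged from 0.00 to 2.39 in HT29, and it lies in the part of chromosome 7 with a median of 0.56 in that line. MAP3K8, a kinase that can activate MEK, was at -0.70 in HT29 and -1.04 in Colo205, with 2 probe sets that ranged from -1.57 to -0.70 and from -1.04 to -0.36, so that its size in either line is not settled. The phosphatase gene DUSP6, a transcriptional readout of ERK activity, was at -0.19 and -0.56. It lies on chromosome 12, where the 725 genes outside the run of BCAT1 had a median of -0.26 in Colo205. The DNA methyltransferase gene DNMT1 was at -0.14 and -0.03.

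Cholesterol biosynthesis genes were lower together in both resistant lines. Of 18 measured genes, 15 were lower in both, with medians of -0.49 in HT29 and -0.47 in Colo205, between the same arrays on which the poly-A spike controls had medians of -0.43 and -0.72 and mitochondrially encoded transcripts 0.51 and 0.47. INSIG1, which retains the sterol-sensing complex in the endoplasmic reticulum, was at -2.76 and -0.96, MSMO1 at -0.71 and -1.15 and DHCR7 at -0.98 and -0.77. Camera called the list (adjusted p = 8.4e-06), and it had adjusted p = 0.999 with an estimated correlation. That correlation was -0.046, below the preset 0.01. With 1 residual degree of freedom it reflects only the signs of the genes' residuals. It therefore cannot show whether the genes were correlated, nor whether correlation raised the call. With an estimated correlation the test has 1 residual degree of freedom and can hardly call a list. Adjusted over the list alone 0 members passed the threshold, and 0 over all genes.

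The ATF4 and unfolded protein response list was also lower in both lines (adjusted p = 1.6e-05), with 15 of 25 genes lower in both and a median of -0.31 in HT29. It too had adjusted p = 0.999 with an estimated correlation. That estimate was 0.44 for this list and likewise reflects only the signs of residuals. DDIT4 was at -1.20 in HT29 and -2.71 in Colo205, and ASNS, asparagine synthetase, at -1.02 and -1.83, while the cystine transporter gene SLC7A11 was at 0.43 and 0.06 and the chaperone gene HSPA5 at 0.16 and 0.14. WNT targets and intestinal stem cell genes were lower (adjusted p = 0.0190, and adjusted p = 0.999 with an estimated correlation), with medians of -0.29 and -0.30 and 8 of 18 genes lower in both. Both lists were lower between the same arrays on which the poly-A spike controls had medians of -0.43 and -0.72 and mitochondrially encoded transcripts 0.51 and 0.47. Beside PROM1, the stem cell receptor gene LGR5 was at -3.43 in HT29 and 0.12 in Colo205, and SMOC2 at 0.15 and -2.48. Adjusted over the list alone 0 members of either list passed, and 0 over all genes.

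Camera also called 2 lists as higher, between those same arrays. The NRF2 and xenobiotic metabolism list (adjusted p = 0.00795, and adjusted p = 0.999 with an estimated correlation) had 11 of 21 genes higher in both lines, with medians of 0.03 in HT29 and 0.52 in Colo205. Its mean was -0.04 in HT29 alone, where 12 of the 21 were higher, and 0.47 in Colo205 alone. GCLM, a subunit of the first enzyme of glutathione synthesis, was at 0.49 and 1.26, and ALDH1A1 at -1.74 and 0.14. The mesenchymal list (adjusted p = 0.0186, and adjusted p = 0.999 with an estimated correlation) had medians of 0.16 and 0.18 over 14 genes. Without TNC, a choice made after seeing the data, its adjusted p was 0.118. FAP was at 0.54 and 0.19, VIM at -0.23 and 0.17 and S100A4 at -0.55 and 0.49. TNC was the 1 member that passed adjusted over the list alone, and 0 passed over all genes.

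**Figure D3:**
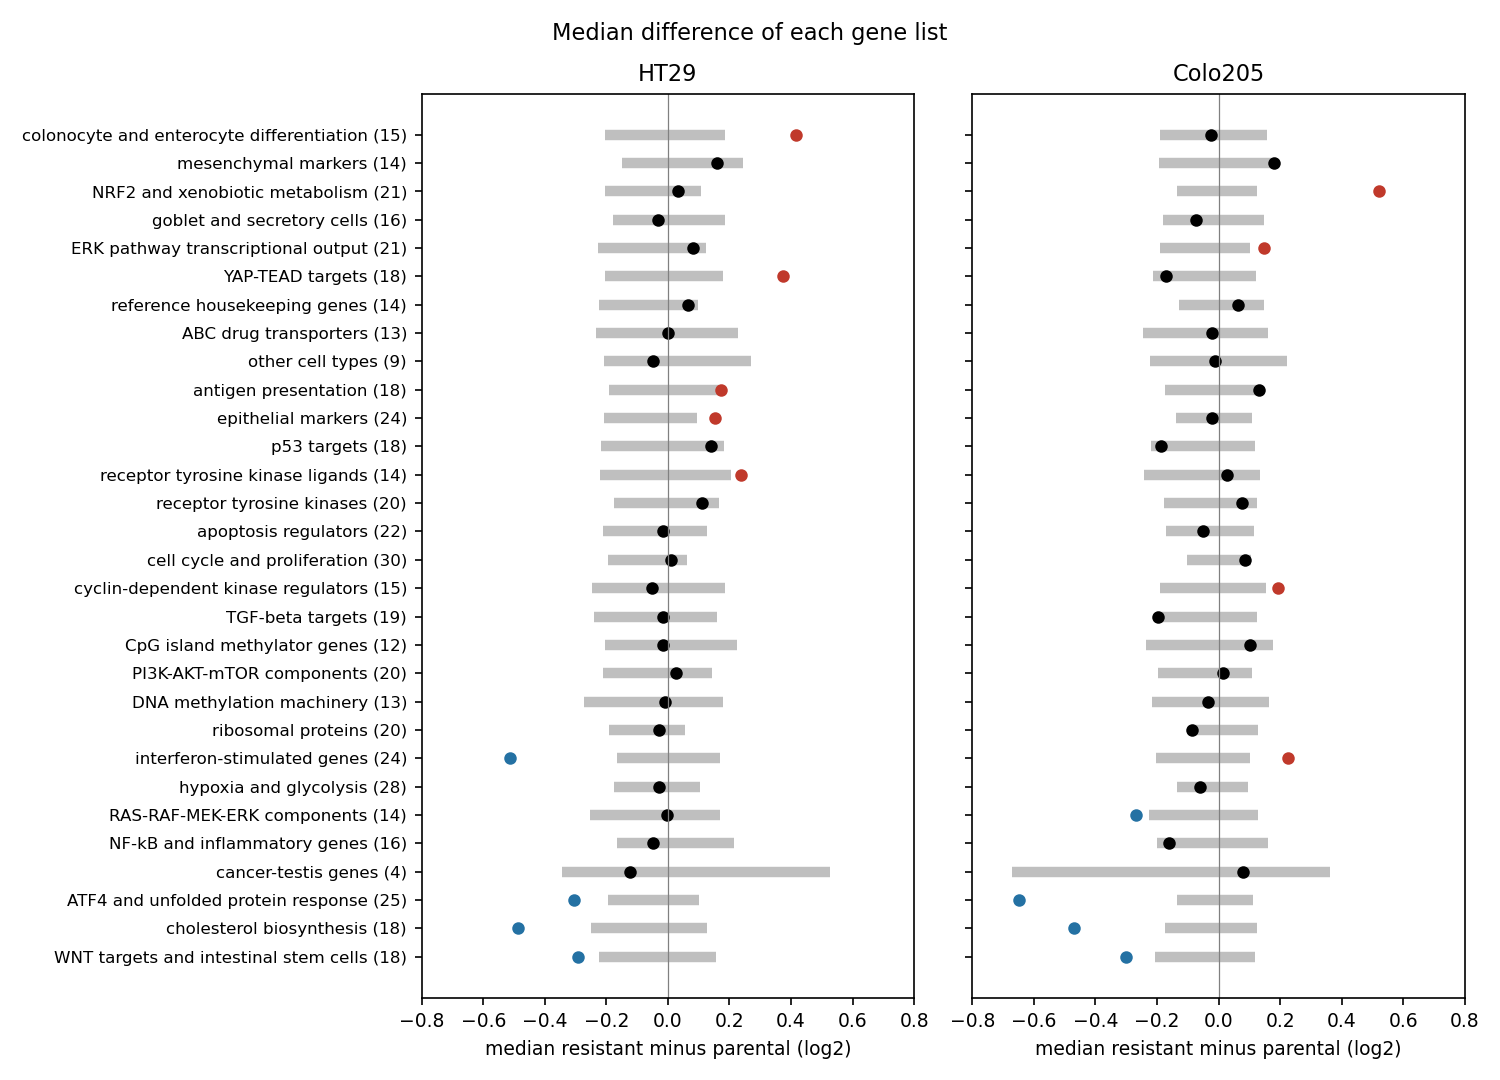
Median resistant minus parental log2 difference of each of the 30 gene lists in HT29 (left) and Colo205 (right), with the number of measured genes in brackets. Grey bars span the central 95% of 10000 random lists, points above them are red and points below are blue, and the cholesterol list lies at -0.49 and -0.47.

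The other 25 lists were not called by camera. Colonocyte and enterocyte differentiation had adjusted p = 0.0748, with CDH17 at 5.94 and 1.37 and medians of 0.42 and -0.02. Interferon-stimulated genes had adjusted p = 0.434, YAP-TEAD targets 0.350 with medians of 0.38 and -0.17, and epithelial markers 0.541 with medians of 0.15 and -0.02. ERK pathway output had adjusted p = 0.537 and medians of 0.08 and 0.15, with FOSL1 at 1.90 and 0.27 and ETV5 at -1.11 and -0.60. RAS-RAF-MEK-ERK components had adjusted p = 0.350 and medians of -0.00 and -0.27. Receptor tyrosine kinases had adjusted p = 0.858 and medians of 0.11 and 0.08, with MST1R at 0.80 and 0.68 and KIT at 0.20 and -2.35, and their ligands had 0.350 with medians of 0.24 and 0.03. Cyclin-dependent kinase regulators had adjusted p = 0.826 and medians of -0.05 and 0.19, with the inhibitor gene CDKN1B at -1.28 and -1.47 and CDKN1A at 1.74 and 0.11. Antigen presentation had adjusted p = 0.347 and medians of 0.17 and 0.13.

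Cell cycle genes had medians of 0.01 and 0.09 (adjusted p = 0.736), with 0 of 30 genes past 2-fold in either line, apoptosis regulators -0.02 and -0.05 (0.961), and p53 targets 0.14 and -0.19 (0.998). PI3K-AKT-mTOR components had medians of 0.03 and 0.02 (0.998), TGF-beta targets -0.01 and -0.20 (0.736), NF-kB and inflammatory genes -0.05 and -0.16 (0.692), and hypoxia and glycolysis genes -0.03 and -0.06 (0.980). PMEPA1, a TGF-beta target, was at 1.99 and 1.41, and VEGFA, in the hypoxia list, at -0.44 and -1.86. ABC drug transporters had medians of 0.00 and -0.02 (0.537), with ABCG1 at 0.76 and 0.98 and ABCB1 at -0.23 and -2.34.

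DNA methylation machinery had medians of -0.01 and -0.04 (adjusted p = 0.980), genes methylated in CpG island methylator colon cancers -0.02 and 0.10 (0.928), and cancer-testis genes, of which 4 of 25 passed the filter, -0.12 and 0.08 (0.998). Goblet and secretory cell genes had medians of -0.03 and -0.07 (0.998), with REG4 as the leading member. Markers of other cell types, from fibroblasts, blood and vessels, were measured for 9 of 22 genes and had medians of -0.05 and -0.01 (0.961). Ribosomal proteins had medians of -0.03 and -0.09 (0.537) and reference housekeeping genes 0.07 and 0.06 (0.537). Over the 30 lists, 5 members passed adjusted over the list alone, namely TNC, CEACAM5, REG4, CDKN1B and PMEPA1, against 0 over all genes. In 13 lists the 2 medians, the mean and the direction of the camera test did not share a sign, the colonocyte, interferon and YAP-TEAD lists among them. Fry called 0 of the 30 lists (smallest adjusted p = 0.164).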

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

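The tests of the chromosome 7 parts in Colo205 and in left-out genes, of gene copies and of single genes' probe sets on chromosome 12, and all those given for the shared differences were chosen after the result was seen. For RNA of the other line, 1 test of both lines together had been set before; it decided nothing, because of the value of 0.38 given below for HT29, and it was then divided by line and by gene. The test of the chromosome 12 probe sets was set for the whole run before and was likewise divided by gene.

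Several genes differed in opposite directions in the 2 lines, which was not tested since each line has 1 array per status. TIMP2, an inhibitor of matrix proteases, was at 2.90 in HT29 and -3.23 in Colo205, a gap of 6.13 on the log2 scale. FABP1, the liver and intestinal fatty acid binding protein, was at 2.30 and -2.17 (a gap of 4.47), FOXD1 at 1.70 and -2.05 (3.75), the zinc transporter gene SLC30A4 at 1.97 and -1.55 (3.51) and TCEAL9 at 1.47 and -2.78 (4.26). The other way round, IQGAP2 was at -1.86 and 1.77 (a gap of -3.64), IFIT1 at -1.66 and 2.80 (-4.46), IFI44 at -1.65 and 1.54 (-3.20), IFI27 at -1.24 and 3.40 (-4.64) and the clock gene PER3 at -2.30 and 1.02 (-3.32). The probe sets of TIMP2 ranged from -3.23 to -1.09 in Colo205 and those of PER3 from -2.30 to -0.30 in HT29. The interferon-stimulated list had medians of -0.51 and 0.22, a gap of -0.74, with 7 of its 24 genes lower in both lines and 1 higher in both. Among probe sets without a gene name, which entered no comparison, 5 of 3965 past the filter were 2-fold or more higher than the parent in both lines, against 1.08 for independent lists.

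In resistant HT29 the genes of chromosome 7 split along the chromosome. The first 221 genes in order, up to CRCP, had a median difference of 0.56 with 86.9% higher, and the remaining 417 had a median of -0.21. Brightness and a probe effect of the array do not account for the split, since removing a trend on mean expression left a gap of 0.80 against 0.77 and the same parts of Colo205 differed by 0.00240. With the split placed on every other gene, the left-out genes differed by 0.78, which is what unequal gene dosage would give, but the chromosome was picked for this pattern and no DNA was measured, so dosage stays a hypothesis. Of the 467 genes higher in HT29, 57 lay in the first part, EGFR and SNX10 among them, and 397 of the 467 lay outside chromosome 7.

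In resistant Colo205 a run of 8 neighbouring genes on chromosome 12, from LDHB to ETFRF1, held 7 genes that were 2-fold or more higher, while the other 725 genes of that chromosome had a median of -0.26. A faulty probe set is argued against for ETNK1, BCAT1 and ETFRF1, whose other probe sets had medians of 2.89 or more, but stays open for IRAG2 and DNAI7, which had no other probe set past the filter, and for LDHB and CMAS, whose second probe sets were at -0.48 and 0.77, so that 0 of these 4 had another one at 2-fold or more. HT29 RNA in the sample is argued against by 4 genes of the run that lay above both HT29 arrays by 1 or more. The run was picked for its higher genes, so the 87.5% of its genes past 2-fold cannot speak for a gain of gene copies. Such a gain may give a run like this, but C2CD5 inside it was at 0.04 and shared regulation would look alike. Without a measurement of DNA the gain cannot be told apart from regulation.

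For the differences shared by both resistant lines, HT29 RNA in resistant Colo205 is argued against by the 42 genes that only HT29 expressed, whose median in Colo205 was 0.0433, and Colo205 RNA in resistant HT29 by 28 of the 40 genes higher in both, which lay above both Colo205 arrays. Each of the other 12 would need between 2.90% and 84.3% of Colo205 RNA, which predicts a median of at least 1.01 in HT29 for the 78 genes that only Colo205 expressed, and these had a median of 0.38 with an upper quartile of 0.73. A share of 0.870%, which would give that 0.38, stays open but would lift 0 of the 12 by 2-fold or more. It would lift SPRR3 by 0.88, beside a measured 3.13, and GPA33 by 0.52, beside a measured 1.28. Of the 78 genes that only Colo205 expressed, 12 were 2-fold or more higher in HT29. Loss of 5' ends is argued against by the 3' minus 5' gap of ACTB, which differed by -0.37 in HT29 and 0.25 in Colo205. The poly-A spike controls had medians of -0.43 and -0.72, and such a processing difference cannot be told apart from resistance, since it lies between the same arrays; acquired resistance, the difference the design names, stays open and untested.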

How the results depend on the processing

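The runs without chromosome 7 genes and without TNC were chosen after seeing the data; the others were planned. Of the counts, correlation and list calls set against an alternative, 76 stayed within 1.5 times or within their interval and 21 moved. A threshold of 1.5-fold gave 1106 higher and 941 lower genes in HT29, 408 and 1062 in Colo205, 131 higher and 187 lower in both, and 151 in opposite directions. At 3-fold these were 157 and 64, 50 and 107, 14 and 5, and 5. The mean over a gene's probe sets gave 145 lower genes in HT29, 26 higher in both and 19 in opposite directions. A filter at the 75th percentile gave a correlation of 0.20 between the lines. Without the replicate block camera called 3 lists, losing the WNT and NRF2 lists and keeping the other 3. With the block and an estimated correlation it called 0, as did fry. Camera with an estimated correlation has 1 residual degree of freedom, so it can hardly call a list. The NRF2 list mean ranged from -0.0430 with Colo205 left out to 0.467 with HT29 left out, so the sign of the mean, though not of the HT29 median of 0.03, turns without Colo205. Its call was also lost with no filter, the mesenchymal call with a filter on the mean, without the ambiguous probe sets and without TNC, and the WNT call with probe set means, while the colonocyte list was called with the 75th percentile filter. The cause was not tested. Without chromosome 7 genes HT29 had 397 higher and 214 lower genes. Limma called 0 genes under every setting run. Of the named genes' values, 482 stayed within the scatter between probe sets and 92 moved beyond it. A change of direction was counted only for values of 2-fold or more, and 0 of these changed. That 0 was largely set by the choice of genes. Those ranked in each line had probe sets that pointed the same way, and those shared had lines that did. Smaller values were not checked for it. Of the values for gene lists, 654 stayed the same, 105 moved, 17 lost and 1 gained a call, and 1 reversed. A reversal was counted only for the means of called lists. The alternatives on the pseudocount were not run, since the table is on a log scale. Leaving out 1 line leaves no residual degrees of freedom and so gives values without a test. Signal over background limits genes near the filter value of 5.73.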

Other observations

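The families in this part were chosen after their values were seen, and each holds all members past the filter. The higher SPRR genes belong to a stretch of chromosome 1 that holds genes of squamous differentiation. Of 28 neighbouring genes from MRPL9 to S100A1, 6 were 2-fold or more higher in HT29 and 6 in Colo205, and 0 were 2-fold or more lower in either. S100A11 was at 1.05 in HT29 and 1.04 in Colo205. The hair follicle protein gene TCHH was at 0.74 and 1.06. SPRR2B, between the higher genes, was at -0.21 and -0.03. Of 11 annexins, 7 were higher in both lines and 1 lower in both, with ANXA1 at 1.18 and 1.76 and ANXA9 at -0.93 and -1.74. Of 12 calpains, 4 were higher and 4 lower in both, with CAPN8 at 2.15 and 1.09, CAPN2 at 1.45 and 1.05, CAPN12 at -1.88 and -0.37 and CAPN6 at 0.18 and -2.42. Of 4 serpin B genes, 3 were higher and 1 lower in both, with SERPINB5 at 1.41 and 1.30 and SERPINB9 at -1.10 and -0.20.

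Homeobox genes of the HOXB cluster were mostly lower. The 10 measured genes had medians of -0.53 in HT29 and -0.54 in Colo205, and 6 of them were lower in both lines, with HOXB3 at -0.90 and -1.48. HOXB2 was at 0.24 and -0.60, and HOXB13 at 0.19 and -0.48. HOTAIR, a long noncoding RNA of the HOXC cluster that was chosen after its value was seen, was at -1.26 in both. The 6 measured HOXC genes had medians of -0.16 in HT29 and 0.10 in Colo205, with 2 lower and 1 higher in both. Metallothioneins had medians of -0.43 and -0.73 over 6 genes, 4 of them lower in both lines, with MT1X at -0.71 and -0.65. MT1E, at -1.20 and 0.45, and MT1G, at 0.14 and -0.93, went opposite ways. The poly-A spike controls had medians of -0.43 and -0.72 between the same arrays. Of 22 keratins, 12 were higher and 3 lower in both lines, with medians of 0.20 and 0.10, and no difference between the lines was tested. Among those that went opposite ways were KRT80, at 1.39 in HT29 and -0.42 in Colo205 and KRT23, at 1.47 and -0.79.

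Medians over windows of 25 neighbouring genes were set against 1000 shuffles of the gene order. In HT29, 112 windows lay above and 77 below the most extreme shuffle. Of these, 110 and 63 were on chromosome 7 and 11 of the lower ones on chromosome 13. In Colo205, 4 windows lay above, all on chromosome 1, and 46 below, with 38 on chromosome 12. The genes of chromosome 15 had a median of -0.23 in Colo205 and 0.02 in HT29, and 25.5% of them were higher in Colo205.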
